A study of Arabidopsis thaliana with 12 samples.

How the data were processed

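Gene expression was measured by RNA sequencing of oligo(dT)-selected RNA from seedling shoots, in 3 replicates each of Col, C24, Col/C24 and C24/Col. Alignment with TopHat to the TAIR10 genome is stated per the submitters' processing notes. The counting tool, the annotation version and whether reads or fragments were counted are not given in the sources used here. The authors deposited 1 file per library without a header, with a gene identifier and a value of 2 decimals. The unit of the deposited values was read from the values as RPKM, since for genes with few reads the value multiplied by gene length took multiples of 1 constant per library. This spacing also gave the depth, from genes of 150 to 600 bp. Estimated depths were 15.8 to 27.2 M reads, and 68.7% to 79.1% of the low values came out whole within a tolerance of 0.15 of a read. These counts were not used as data, and intervals from them would cover counting error only.

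Each file held 34133 lines with 33559 distinct identifiers. The 567 identifiers that occurred more than once (1141 lines, nearly all pseudogenes) were left out, since their values could not be told apart, which left 32992 genes. Of the identifiers, 32815 matched a gene of TAIR10.1, which served for symbols (10303 genes) and lengths. No coordinates are given, because the annotation the authors used is not stated. Splicing and allele-specific expression were not analysed here, since the values are per gene.

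Computation used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. A count model had been planned, with limma on log values as the stated fallback for normalized values, and the fallback was used because the deposited values are RPKM. Values were used as deposited on the scale log2(RPKM + 1), on which a fold change understates the change of low genes. Genes with at least 1 RPKM in at least 3 libraries (17927) entered a linear model per gene with moderated variances and a mean-variance trend. All 12 libraries were fitted together for C24 against Col, for the reciprocal hybrids and for genes outside both parents. Mid-parent profiles were the mean RPKM of the Col and C24 libraries of the same replicate number and were fitted with the 6 hybrid libraries. P-values were adjusted by Benjamini and Hochberg over the genes tested, with a threshold of 0.05. Nothing states that replicates were separate plants or pools, so that p-values measure the spread between these samples. Ratios in folds are of mean RPKM.

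Replicate numbers were checked for pairing before fits were compared. Deviations from the group means correlated at 0.54 to 0.83 over the 18 pairs of libraries with the same number, and at -0.65 to 0.19 over the 36 pairs with different numbers. The numbers therefore paired the samples by the data, while the labels say nothing of a shared batch or day. The fit with the number as a block is given beside a result where it changed a call or a count.

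Gene lists were fixed before the data were examined, 20 lists with 414 members of which 401 matched by symbol. They covered glucosinolate, flowering time, flavonoid, jasmonate, salicylic acid, immune receptor, cold and drought, cell division, splicing factor, photosynthesis, chlorophyll, clock, auxin, DNA methylation, heat shock, touch, senescence, root, flower and seed storage genes. Of these 18 had enough tested members for camera (preset correlation 0.01, and again with an estimated correlation) and fry, adjusted over lists within a comparison. Some genes, such as MYB28, ESM1 and CYP83B1, were named outside any rule, and the others were chosen by a rule fixed beforehand. It takes the 8 largest rises and falls per comparison among passing genes with a symbol, at least 5 RPKM in the higher group and no overlap between replicates, and up to 3 passing members per list. A list without a passing member gives its 2 members with the highest means. For genes outside both parents it takes the 6 highest and 6 lowest by the smaller fold change.

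The models were tested on simulated data in which 200 of 17927 genes were changed by known folds of RPKM + 1. Without the block 83.4% of 2-fold and 95.8% of 4-fold changes were recovered for C24 against Col, and 83.0% and 94.2% for the reciprocal hybrids. Alternatives covered the filter, a 2-fold minimum, organelle genes, the samples in the fit, the replicate block, the mid-parent (geometric, or other pairs) and each replicate left out. A pseudocount of 0.1, median-of-ratios scaling of the values, the ribosomal RNA share as a covariate and the removal of the 4 libraries above 2% ribosomal RNA were added after the data had been seen. That removal leaves 1 library each of Col and Col/C24 and 1 mid-parent profile, which are assumed to vary like the other groups.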

Results

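Polyadenylated RNA was sequenced from Arabidopsis thaliana shoots harvested at 14 days, from the accessions Col and C24 and from their hybrids in both directions of crossing. The hybrids carry the label names Col/C24 and C24/Col, and which parent was the mother is not stated in the sources used here. Each of the 4 groups had 3 replicates, which gave 12 libraries with 1 RPKM value (reads per kilobase of gene per M mapped reads, M being 1e6) per gene. The plants grew in short days of 8 h light at 22 °C and 16 h darkness at 18 °C. Depths estimated from the spacing of the lowest values ran from 15.8 M reads in C24/Col replicate 3 to 27.2 M in Col replicate 2. At these depths 3 reads on a gene of 1500 bp correspond to 0.07 to 0.13 RPKM, a limit that covers counting error only. Between 17082 and 17420 genes per library reached 1 RPKM.

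Parents and hybrids separated along the first principal component, which held 43.5% of the variance, with Col at -42.15 to -30.67, C24 at 31.57 to 53.9 and the hybrids between them. The second component held 26.8% and set the 4 libraries of replicate 1 (21.48 to 35.27) apart from the other libraries (-29.67 to -5.09). In limma 8 of 9 heat shock, 6 of 6 touch and 12 of 18 salicylic acid defence genes were higher in the 4 libraries of replicate 1 than in replicates 2 and 3. By camera with an estimated correlation these lists had adjusted p = 0.132, 0.132 and 0.184. HSP70, a heat-induced chaperone, averaged 126 ± 95.1 RPKM in them (SD, n = 4) against 15.2 ± 9.59 and 16.5 ± 9.72 in replicates 2 and 3. Ribosomal RNA genes took between 0.23% and 4.49% of the summed values. This share exceeded 2% in 4 libraries, Col 1, Col 2, Col/C24 1 and Col/C24 3, and lay between 0.23% and 0.44% in the C24 libraries. It ran from 1.22% to 4.49% in Col/C24 and from 0.32% to 1.18% in C24/Col, so that it differed with the direction of crossing too. The share of plastid genes rose with that of ribosomal RNA, from 0.27% in C24 2 to 4.31% in Col/C24 3. A covariate of the ribosomal RNA share therefore stands for both.

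**Figure D1:**
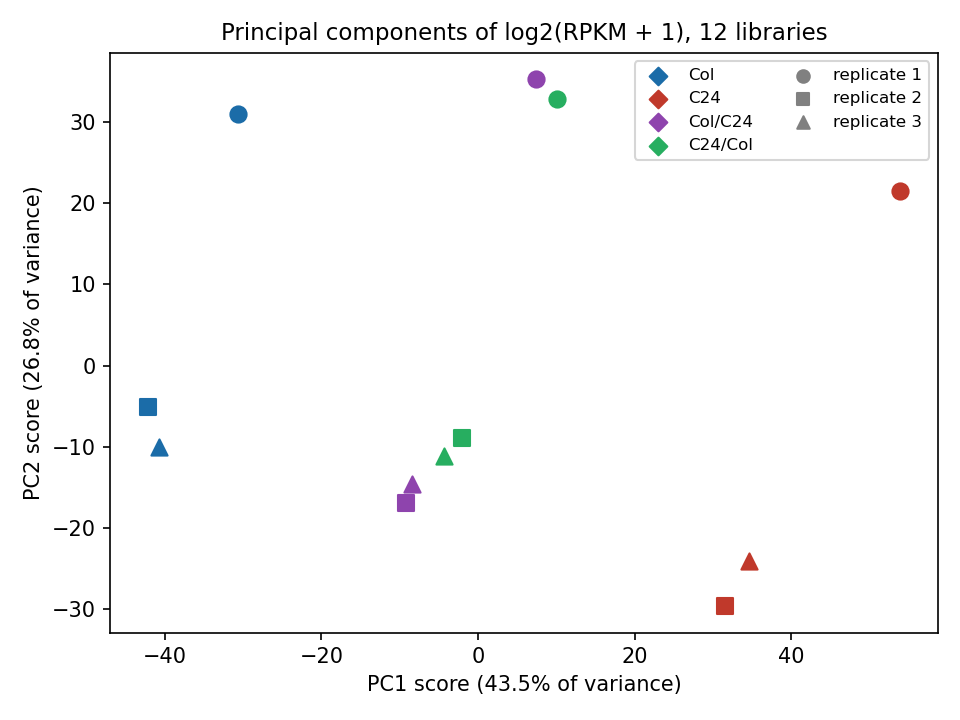
Scores of the 12 libraries on the first and second principal components of log2(RPKM + 1), with colour for the group and symbol for the replicate. The first axis (43.5% of variance) orders Col, hybrids and C24, and the second (26.8%) sets the libraries of replicate 1 above the others.

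**Figure D2:**
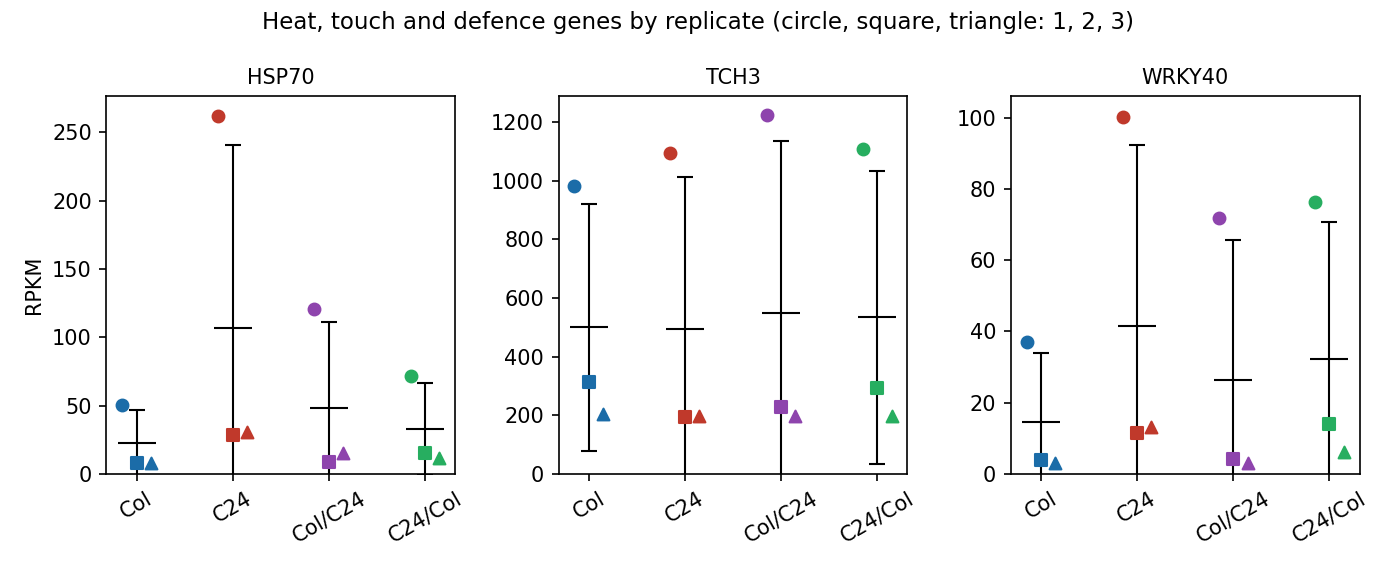
RPKM of HSP70, TCH3 and WRKY40 in each library (points) with group mean and SD (lines, n = 3). In every group the circle, replicate 1, is the highest point.

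The parents were compared first, since the accessions differ in growth and the hybrids are read against them. Several genes that make or break down glucosinolates, sulphur-containing defence compounds, had far more transcript in C24 shoots. Transcripts of AT1G54040 (ESP), whose product steers glucosinolate breakdown towards nitriles, stood at 2758 ± 163 RPKM in C24 and 12.7 ± 1.08 in Col (SD, n = 3), a 217.5-fold difference (log2 fold change 7.66, SE 0.09, limma adjusted p = 2.26e-12). AOP2, a side-chain-modifying enzyme of the pathway, stood at 317 ± 48.6 RPKM in C24 and 1.48 ± 0.671 in Col (log2 fold change 7.03, SE 0.2, adjusted p = 8.12e-10). Of 27 measured glucosinolate genes, 17 were higher in C24, 2 were lower and 8 did not pass. Those higher included BCAT4 (163 ± 23.3 against 36.0 ± 3.21 RPKM), the regulator MYB28 (25.8 ± 5.33 against 10.4 ± 1.48) and the myrosinase TGG1 (2163 ± 184 against 1305 ± 80.1). ESM1, which acts against ESP, was lower in C24 at 34.9 ± 6.06 RPKM against 204 ± 45.9, as was CYP83B1. The list as a whole lay above other genes (camera adjusted p = 1.03e-09), but not with an estimated correlation between genes (adjusted p = 0.517).

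Flowering-time regulators differed between the parents one by one, with 2 of 21 measured genes higher in C24, 6 lower and 13 not passing. FLC, a repressor of flowering, stood at 94.4 ± 8.91 RPKM in C24 and 2.17 ± 0.261 in Col (43.5-fold, log2 fold change 4.91, SE 0.1, adjusted p = 7.53e-11). Its relative MAF1 (FLM) went the other way, at 3.22 ± 0.458 RPKM in C24 and 30.01 ± 3.87 in Col (log2 fold change -2.87, adjusted p = 6.9e-09). AGL20 (SOC1), a promoter of flowering that FLC represses, was lower in C24 (11.4 ± 2.80 against 34.98 ± 4.73 RPKM), and so was VRN2 (7.81 ± 0.427 against 13.4 ± 0.196). FRI, an activator of FLC, stood at 3.62 ± 0.465 RPKM in C24 and 3.47 ± 0.259 in Col (adjusted p = 0.783). The list had no common direction (camera adjusted p = 0.76).

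Of 12 measured flavonoid and anthocyanin genes 6 were lower in C24 and none higher, with 8 lower when adjusted over the list alone, and 1 higher and 9 lower with the replicate as a block. They were led by UGT78D1 (1.77 ± 0.251 against 13.3 ± 1.27 RPKM), DFR (3.59 ± 0.656 against 11.5 ± 2.68) and TT7 (0.37 ± 0.0361 against 1.34 ± 0.388). TT4 (CHS), the entry enzyme of the pathway, stood at 8.11 ± 1.69 against 15.1 ± 2.68 RPKM. The camera test gave adjusted p = 0.00264, and adjusted p = 0.614 with an estimated correlation. Of 21 measured jasmonate genes, 6 were higher in C24 and 1 was lower (7 and 1 when adjusted over the list alone). The biosynthetic enzyme LOX2 stood at 278 ± 73.5 RPKM in C24 against 75.3 ± 10.8 in Col, while VSP2, a late response gene, stood at 11.3 ± 2.06 against 24.6 ± 4.11. The list's camera adjusted p was 0.0171 (0.995 with an estimated correlation), and it rose to 0.115 without Col replicate 3 and to 0.265 without C24 replicate 1. With the replicate as a block 11 jasmonate genes were higher and 1 was lower.

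Among immune receptor genes 3 of 21 were higher in C24 and 4 were lower (8 and 7 with the replicate as a block). RLM3 stood at 14.0 ± 1.02 RPKM in C24 against 126 ± 25.97 in Col and RPP8 at 21.9 ± 1.19 against 40.8 ± 1.70. Lower values in C24, for these and other genes, may also come from C24 reads lost in mapping, which was not tested. RPM1 was listed at 0 in all 3 C24 libraries and at 9.11, 4.59 and 5.05 RPKM in Col. Of 18 salicylic acid defence genes 2 were higher and 1 was lower, with BGL2 (PR2) at 5.21 ± 0.639 RPKM in C24 against 0.507 ± 0.227 (log2 fold change 2.05). With the ribosomal RNA share as a covariate the BGL2 call was lost (1.2, adjusted p = 0.279). The calls of WRKY70 (higher) and ACD6 (lower) were lost without Col replicate 2 (limma adjusted p = 0.14 and 0.0568). With the replicate as a block 9 salicylic acid genes were higher and 2 were lower (camera adjusted p = 0.0165, and 0.84 with an estimated correlation). Cold and drought genes split into 4 higher and 3 lower of 16 (5 and 6 with the block), with KIN2 at 65.2 ± 3.92 RPKM in C24 against 303 ± 76.6.

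Of 27 measured cell division genes 8 were lower in C24, 2 were higher and 17 did not pass. Those lower included the cytokinesis syntaxin SYP111 (KNOLLE; 16.7 ± 1.81 against 31.6 ± 2.70 RPKM) and the mitotic kinase CDKB2;1 (11.7 ± 0.393 against 16.6 ± 1.07). Adjusted over the list alone 2 were higher and 10 lower, and 3 and 12 with the replicate as a block. Of 31 splicing factor genes 7 were lower and none higher (9 lower when adjusted over the list alone; 2 higher and 14 lower with the block), with PTB2 at 18.0 ± 1.11 RPKM in C24 against 22.4 ± 0.621. Both lists had a camera adjusted p of 0.0379, and 0.995 with an estimated correlation. The cell division value ranged from 0.0216 without Col replicate 3 to 0.0928 without Col replicate 2, and the list did not pass either without Col replicate 1 (0.0566), C24 replicate 1 (0.0635) or C24 replicate 3 (0.0767). The splicing value rose to 0.211 without Col replicate 3, to 0.132 without C24 replicate 1 and to 0.0535 without C24 replicate 2.

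Of 42 measured photosynthesis genes 4 were higher in C24 and 2 were lower, such as LHCA3 at 2770 ± 154 RPKM against 4033 ± 417 (with the block 14 were higher and 3 lower). The list's camera adjusted p was 0.0148 with a median log2 fold change of 0.17, and 0.995 with an estimated correlation. The ribosomal RNA share, which also separated C24 from Col, took that median to -0.002 and the p to 0.937 when it entered the fit as a covariate. The camera p was 0.219 without Col replicate 1 and 0.0535 without C24 replicate 2. In chlorophyll synthesis 2 of 15 genes were higher and 1 lower (5 and 2 with the block), led by HEMA1, which catalyses its first committed step (349 ± 34.4 against 199 ± 37.0 RPKM). Of 19 clock genes RVE1 was lower in C24 (0.943 ± 0.0322 against 3.84 ± 0.573 RPKM) and 1 other was higher, against 3 and 3 with the block. Auxin genes gave 3 higher and 2 lower of 23 (8 and 3 with the block), and DNA methylation and small RNA genes 1 higher and 4 lower of 20, with CMT2 at 12.6 ± 1.07 RPKM in C24 against 8.37 ± 0.473.

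No heat shock gene of 9 passed between the parents. HSP70 averaged 107 ± 134 RPKM in C24 against 22.4 ± 24.3 in Col, values set by the replicate 1 libraries. With the replicate as a block 7 of the 9 were higher in C24 (camera adjusted p = 0.000601, and 0.479 with an estimated correlation), and 5 of 6 touch genes were higher, against 1 without the block (STZ). Of 7 darkness and senescence genes 1 was higher (2 higher and 2 lower with the block). The root marker PYK10 stood at 111 ± 2.01 RPKM in C24 against 80.2 ± 14.0 (log2 fold change 0.47), a call lost with the ribosomal RNA covariate (0.32, adjusted p = 0.181). No other root marker exceeded 1.27 RPKM in any library. Among these PHT1;1 lay lower in C24 (0.03 to 0.05 RPKM against 0.45 to 0.66 in Col). The flower marker SEP3 stood at 3.23 ± 0.447 against 2.24 ± 0.119 (adjusted p = 0.0726, and 0.0268 with the block). No other flower marker exceeded 0.52 RPKM in any library, and no seed storage gene passed.

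Among genes with a symbol, those with the largest falls in C24 by log2 fold change were ECS1 (0.117 ± 0.0416 RPKM against 145 ± 4.69 in Col), LpxC2 (0.01 ± 0.0173 against 82.8 ± 7.61), SADHU1-1 (0.06 ± 0.104 against 67.6 ± 4.92), the arginase ARGAH2 (0.0133 ± 0.0231 against 37.9 ± 5.67) and HR4 (0.51 ± 0.46 against 39.5 ± 21.7). Large rises were also seen in the copper transporter COPT2 (16.6 ± 1.19 against 0.647 ± 0.0839 RPKM), AGL38 (15.2 ± 4.36 against 0.137 ± 0.11) and PCC1 (26.9 ± 16.6 against 1.55 ± 1.25). Reads of LpxC2 and of the SADHU retroelements among the extremes may be shared with similar copies, which was not tested, so that their values are uncertain.

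In total 4071 of 17927 genes tested (22.7%) passed an adjusted p of 0.05 in limma, 1852 higher and 2219 lower in C24, and 929 of them also differed at least 2-fold. With the replicate as a block 7490 passed, which included all 4071. With the ribosomal RNA share as a covariate 2016 passed. The STZ call was lost there at a similar log2 fold change (3.33 against 3.26, adjusted p = 0.0784).

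The reciprocal hybrids were compared to look for effects of the direction of crossing. No gene differed between C24/Col and Col/C24 in limma, with 745 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.747. With the replicate as a block there was again no gene, at a smallest adjusted p of 0.0916 and with 2377 genes at an unadjusted p under 0.05. The unadjusted counts depended on scaling. Under a common scaling of the libraries they were 377 without the block and 1018 with it, at smallest adjusted p of 0.772 and 0.149. Simulated changes of 2-fold and 4-fold in RPKM + 1 were recovered in 83.0% and 94.2% of genes in the same comparison. In that simulation 200 genes were changed at once. Smaller numbers of changed genes were not simulated, so these shares do not show how well a few reciprocal differences would be found. The parental contrasts were even in both hybrids. FLC stood at 94.6 ± 9.36 RPKM in C24/Col and 93.2 ± 6.60 in Col/C24, AT1G54040 (ESP) at 1359 ± 37.1 and 1307 ± 120, and RBCS1A, a small subunit of Rubisco, at 11820 ± 905 and 11760 ± 2134. Camera placed the photosynthesis, cell division and heat shock lists below other genes in C24/Col (adjusted p = 0.00251, 6.93e-06 and 0.0256) and the glucosinolate list above them (0.0256). With an estimated correlation the adjusted p was 0.997 for each, and no member of these lists passed. The photosynthesis list did not pass without C24/Col replicate 1 (0.0785) or 3 (0.0535) and turned upward without Col/C24 replicate 2 (0.0286), where the cell division value was 0.0535. The glucosinolate list did not pass without Col/C24 replicate 1 (0.298) or 3 (0.061) or C24/Col replicate 2 (0.643), nor the heat shock list without Col/C24 replicate 1 (0.808) or C24/Col replicate 2 (0.282) or 3 (0.335). The median of the photosynthesis list was 0.01, of opposite sign to its test, against a median of 0.09 over all genes. Seed storage transcripts were unevenly spread, with CRA1 at 27.6 RPKM in Col/C24 replicate 1, 12.2 in C24/Col replicate 1 and 50.4 in C24/Col replicate 3, and at most 0.48 in the other libraries.

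Each hybrid was then set against the mid-parent, the mean of Col and C24 that additive expression would give. FLC lay at the C24 level in both hybrids, at 93.2 ± 6.60 RPKM in Col/C24 and 94.6 ± 9.36 in C24/Col against a mid-parent of 48.3 ± 4.54 (log2 fold changes 0.94 and 0.96, SE 0.1, limma adjusted p = 0.0313 and 0.0327). AGL20 (SOC1) was lower than the mid-parent, at 5.65 ± 1.25 and 6.22 ± 1.48 RPKM against a mid-parent of 23.2 ± 3.72 (log2 fold changes -1.87 and -1.76, SE 0.2, adjusted p = 0.0313 and 0.038). In both hybrids all 3 replicates showed these directions. AT1G20390 stood at 0.213 ± 0.0416 and 0.237 ± 0.0666 RPKM against a mid-parent of 4.1 ± 0.553, close to the C24 level of 0.01 ± 0.0173 rather than to Col at 8.19 ± 1.1 (log2 fold changes -2.07 and -2.04, adjusted p = 0.000427 and 0.000476). The drought-responsive dehydrin AT5G66400 (RAB18) stood at 64.0 ± 5.97 RPKM in C24/Col against a mid-parent of 38.4 ± 1.65 (log2 fold change 0.72, adjusted p = 0.0455).

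In limma 6 genes (1 higher, 5 lower) differed from the mid-parent in Col/C24 and 9 genes (4 higher, 5 lower) in C24/Col. Besides FLC, AGL20 and RAB18 these were AT1G20390, AT1G67865, AT3G28320 and AT5G45430 in both hybrids, and AT5G34795 and AT5G45428 in C24/Col, all 6 named after their values were seen. AT5G45428 and AT5G45430 are neighbours, and it is uncertain which of them the reads came from. Against the geometric mean of the parents 156 genes (125 higher, 31 lower) and 186 genes (161 higher, 25 lower) passed, AT3G28320 turned to a rise (log2 fold change 0.64 in each hybrid) and AT1G67865 did not pass (-0.13 and 0.11). With the replicate as a block 519 genes (53 higher, 466 lower) and 282 genes (131 higher, 151 lower) passed. The excess of lower genes in Col/C24 depended on scaling, with 65 higher and 61 lower under a common scaling with the block (265 and 317 in C24/Col). Without any single hybrid or mid-parent profile only 1 or 2 genes remained, and AT1G20390 passed in each of these fits. In these fits, run without the replicate block, FLC had an adjusted p of 0.0652 to 0.222, AGL20 of 0.0838 to 0.245 and AT5G66400 (RAB18) of 0.115 to 0.276. With the block and all profiles, the limma adjusted p of FLC was 0.000167 in Col/C24 and 0.00014 in C24/Col. That of AGL20 was 3.44e-06 and 5.95e-06, and that of RAB18 was 0.00664 in C24/Col.

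The hybrids shared 1 higher and 5 lower calls, where unchanged groups simulated against the same mid-parent shared 0 and independent lists would share 0.000223 and 0.00139. Their log2 fold changes correlated across genes at 0.558 (0.371 simulated), with a covariance of 0.0147 (0.0141 simulated). In the fit with the block the covariance simulated was 0.00401, and the calls shared were 43 and 93 (0 simulated, 0.387 and 3.93 for independent lists). The simulated values are what the shared profiles alone bring in this model, and the mid-parent has too few profiles to be split.

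Among the lists, no cell division gene passed over all genes, while 1 was lower in Col/C24 and 8 were lower in C24/Col when adjusted over the list alone. Camera placed the list below other genes with an adjusted p of 0.000236 in Col/C24 and 3.17e-11 in C24/Col, and 0.683 and 0.327 with an estimated correlation. With the block 2 and 5 members were lower. Auxin, immune receptor and seed storage lists lay above other genes in both hybrids by camera (adjusted p = 0.00029, 0.00029 and 0.00438 in Col/C24, and 0.00232, 0.0019 and 0.00227 in C24/Col), as did the photosynthesis (1.3e-05) and flavonoid (0.00438) lists in Col/C24. None of these did with an estimated correlation, where the adjusted p was 0.327 to 0.943, and no member passed without the block. With it 2 flavonoid genes were higher (DFR, TT4) and 1 lower in Col/C24, and in C24/Col 1 flavonoid gene (DFR), 1 auxin gene and 2 immune receptor genes (RLM3, RPP8) were higher. Without Col/C24 replicate 1 the immune receptor (0.565) and seed storage (0.307) lists did not pass in Col/C24, nor did photosynthesis (0.544) and flavonoid (0.0996) genes without Col/C24 replicate 2, or flavonoid genes without mid-parent replicate 3 (0.316). In C24/Col the immune receptor list did not pass without C24/Col replicate 1 (0.622) or mid-parent replicate 3 (0.116), nor auxin (0.0828) and seed storage (0.0646) genes without C24/Col replicate 3. In Col/C24 the glucosinolate list had no member past the test over all genes, 5 lower when adjusted over the list alone, and 9 lower and 1 higher with the block (camera adjusted p = 0.0066, and 0.723 with an estimated correlation). CYP79F1, an early enzyme of the pathway, stood at 13.8 ± 3.14 RPKM there against a mid-parent of 25.1 ± 4.42 (adjusted p = 0.4, and 0.00236 with the block).

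A gene was counted as outside both parents where the hybrid differed from Col and from C24 in the same direction. The adjusted p given is the larger of those against Col and against C24. The mid-parent was compared in a separate fit, in which such a gene need not have passed. VSP2, for example, had a limma adjusted p of 0.169 in Col/C24 and 0.0703 in C24/Col against the mid-parent (0.000618 and 0.000177 with the block). VSP2, the jasmonate-responsive storage protein, lay above both parents in both hybrids, at 41.5 ± 7.12 RPKM in Col/C24 and 47.5 ± 10.3 in C24/Col against 24.6 ± 4.11 in Col and 11.3 ± 2.06 in C24 (smaller log2 fold change 0.73 and 0.92, adjusted p = 0.0363 and 0.0137). AGL20 lay below both parents in Col/C24 (smaller log2 fold change -0.89, adjusted p = 0.0341). In C24/Col its difference from C24 did not pass (-0.78, adjusted p = 0.0685, and 2.92e-05 with the block). LEA7, a desiccation protein gene, stood at 10.9 ± 7.37 RPKM in C24/Col against 0.583 ± 0.309 in Col and 1.15 ± 0.728 in C24 (smaller log2 fold change 2.36, SE 0.52, adjusted p = 0.0246). Seed storage genes summed to 28.43, 0.15 and 150.18 RPKM in C24/Col replicates 1, 2 and 3, and to at most 1.05 in the parents. Whether the LEA7 difference goes with these transcripts was not tested. VTC5, a vitamin C synthesis gene, was lower than either parent in Col/C24 (6.81 ± 1.18 against 14.0 ± 1.52 and 10.9 ± 1.66 RPKM). CDC20.2, which acts in mitosis, was lower in C24/Col (8.30 ± 0.748 against 11.2 ± 0.609 and 12.9 ± 0.964 RPKM).

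In total 20 genes (5 higher, 15 lower) lay outside both parents in Col/C24 and 21 genes (15 higher, 6 lower) in C24/Col, and 293 and 165 with the replicate as a block. Under a common scaling of the libraries the Col/C24 set held 10 higher and 2 lower genes, 7 of them from the original 20, and VTC5 no longer passed (adjusted p = 0.0751). Leaving out single libraries took the Col/C24 count to between 5 (without Col/C24 replicate 1) and 38 (without Col/C24 replicate 2), and the C24/Col count to between 7 (without Col replicate 3) and 20. VSP2 did not pass without Col replicate 2 (adjusted p = 0.106 and 0.0547) or Col replicate 3 (0.127 and 0.0582), nor in Col/C24 without C24 replicate 3 (0.0508), Col/C24 replicate 1 (0.112) or Col/C24 replicate 2 (0.0925), nor in C24/Col without C24/Col replicate 2 (0.0505). AGL20 did not pass in Col/C24 without Col replicate 2 (0.0522), C24 replicate 2 (0.111), C24 replicate 3 (0.126), Col/C24 replicate 1 (0.121) or Col/C24 replicate 2 (0.0583). LEA7 did not pass without C24 replicate 2 (0.0985), C24 replicate 3 (0.065), C24/Col replicate 2 (0.0854) or C24/Col replicate 3 (0.0605). VTC5 did not pass without Col replicate 2 (0.0506), Col replicate 3 (0.0605), C24 replicate 1 (0.105), C24 replicate 2 (0.133), Col/C24 replicate 1 (0.141) or Col/C24 replicate 3 (0.129). CDC20.2 did not pass without Col replicate 1 (0.0514), Col replicate 2 (0.114), Col replicate 3 (0.105), C24/Col replicate 1 (0.111) or C24/Col replicate 3 (0.111). The fits without single libraries had no replicate block. With the block and all libraries, the limma adjusted p was 0.00139 and 0.000341 for VSP2, and 9.7e-06 for AGL20 in Col/C24. It was 0.00987 for LEA7 in C24/Col, 0.0032 for VTC5 in Col/C24 and 0.00179 for CDC20.2 in C24/Col.

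**Figure D3:**
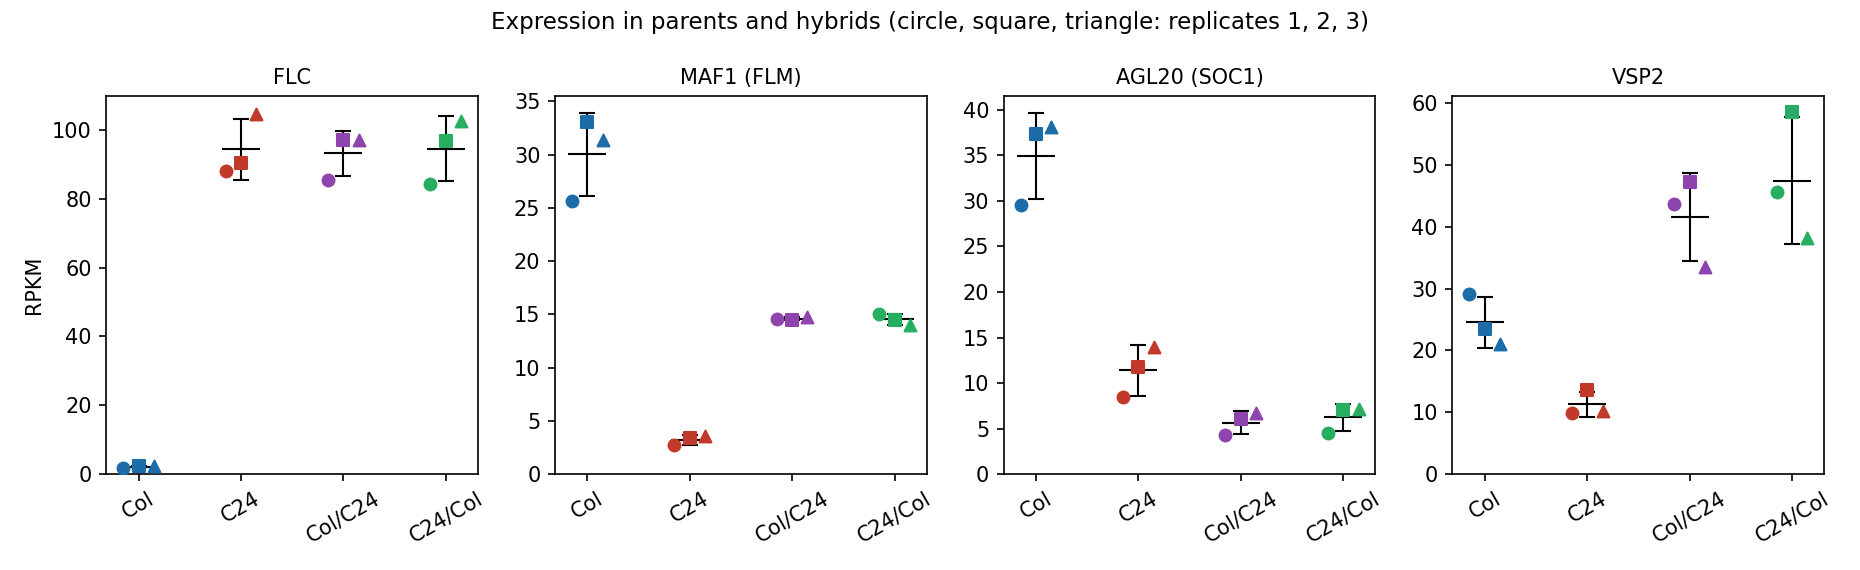
RPKM of FLC, MAF1, AGL20 and VSP2 in each library (points) with group mean and SD (lines, n = 3). FLC lies at the C24 level in both hybrids, MAF1 between the parents, the AGL20 means below and the VSP2 means above those of both parents.

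The position of the hybrids between the parents was taken over genes that passed between Col and C24 and whose mean RPKM differed at least 2-fold, on a scale from 0 at the Col level to 1 at the C24 level. In Col/C24 the median was 0.564 (SD of replicates 0.029) over 675 genes higher in Col and 0.404 (SD 0.042) over 680 genes higher in C24, both on the side of the lower parent. These sets hold more genes than the 929 above, whose 2-fold limit applied to RPKM + 1. In C24/Col the medians were 0.528 (SD 0.021) and 0.482 (SD 0.05). Between 77.3% and 86.0% of genes lay between 0.25 and 0.75 in the 4 sets. MAF1 is an example, at 14.6 ± 0.146 and 14.5 ± 0.49 RPKM in the hybrids against 30.01 ± 3.87 in Col and 3.22 ± 0.458 in C24. Under a common scaling of the libraries the Col/C24 medians were 0.513 and 0.455. Of the hybrids Col/C24 also had the higher ribosomal RNA shares, whose part in these medians was not tested.

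**Figure D4:**
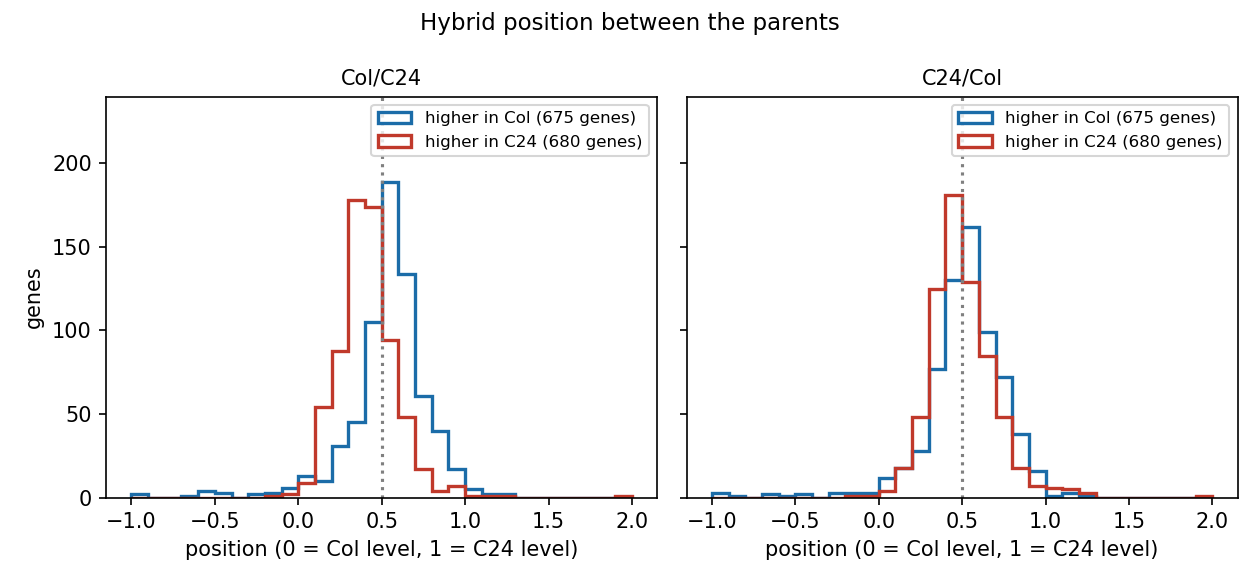
Histograms of hybrid position (x axis, 0 is the Col level and 1 the C24 level) for 675 genes higher in Col and 680 genes higher in C24, with values outside -1 to 2 drawn at those limits. Most genes lie near 0.5, and in Col/C24 the sets lean to opposite sides.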

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

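The tests of ribosomal RNA, depth and heat or handling stress on the replicate pattern, of ribosomal RNA on the parental calls, both tests on genes near 0 in 1 parent, and the splits that part every replicate pair for genes outside both parents were chosen after the result was seen. The clock test and the other counts of splits were fixed before their results. The tests of ribosomal RNA and depth on the replicate pattern replaced rank correlations that had been seen. Those were -0.05 for ribosomal RNA and -0.22 for depth, with upper bounds of 0.61 and 0.71 on their size, which left both explanations open.

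The 4 libraries of replicate 1 deviated together in all groups, with 6116 of 17927 genes called between replicate 1 and replicates 2 and 3. Ribosomal RNA and depth as its cause are argued against, since the median absolute log2 fold change of the called genes kept 0.997 of its size with the ribosomal RNA share as a covariate and 0.998 with depth. Heat or handling stress in the plants of replicate 1 may account for part of it, as 14 of 15 heat shock and touch genes were higher (one-sided Fisher's exact p = 1.49e-10, against 16.6% of all genes), though that test takes genes as independent and camera with an estimated correlation gave an adjusted p of 0.132 for each list. A shared time of harvest or growth batch cannot be told apart, because 42.1% of clock genes differed, above the share set beforehand, but so did 34.1% of all genes (Fisher's exact p = 0.474, a comparison added after the result). No group of the design follows the replicate number, so no group difference was tested as an explanation.

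Ribosomal RNA carry-over was weighed for the parental calls because the share differed between C24 and Col. With the share as a covariate the median absolute log2 fold change of the 4071 called genes was 0.58 against 0.569, a ratio of 1.02, with the sign kept in 100% of them. This argues against carry-over as the whole cause. With the covariate 2016 calls were left. The median SE rose from 0.111 to 0.157, as the share and the parent overlap. Some differences also became smaller, such as those of BGL2 and PYK10, so that not every lost call comes from the larger SE alone. The genetic difference between the accessions stays open, untested.

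Of the genes with at least 5 RPKM in 1 parent, 66 lay below 0.1 RPKM in C24 and 26 in Col, a ratio of 2.54. This is consistent with counting against the Col annotation, in which genes specific to C24 have no entry. The hybrids stood at a median of 0.47 of the expressing parent, with 97.3% of values between 0.25 and 0.75, which is consistent with a loss of expression or of mapping that acts on each allele separately. Deletion, silencing and lost mapping cannot be separated by these values. Among the 5 values outside that range were those of AT1G20390 and BHLH101, an iron-deficiency regulator (7.003 RPKM in Col, 0.04 in C24, 1.07 and 0.963 in the hybrids).

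Outside the genes analysed, 21 lines of repeated identifiers reached 1 RPKM in at least 3 libraries, above the limit that 3 reads set. Lists that differed between the hybrids by camera were photosynthesis (adjusted p = 0.00251), glucosinolate (0.0256), cell division (6.93e-06) and heat shock (0.0256), none of which did with an estimated correlation (0.997 for each).

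With 3 profiles against 3 there are 10 splits, too few for a share under 0.05. The real split was the only 1 as large for C24 against Col (4071 genes, highest other 0), for Col/C24 against the mid-parent (6, highest other 1) and for C24/Col against the mid-parent (9, highest other 0). Between the hybrids all 10 splits gave at least the real count of 0, and the highest other, 13, set Col/C24 1, C24/Col 1 and C24/Col 3, the libraries high in seed storage transcripts, against the rest. Among the 4 splits that part every replicate pair, the blocked fit gave 7490, 0, 519 and 282 genes for the real splits against highest others of 0, 0, 0 and 2. For genes outside both parents 3 of 100 splits gave as many as the real 20 in Col/C24 and 3 of 100 as many as the real 21 in C24/Col, the real split included. The highest others were 548 and 934. The other splits as large put all 3 libraries of 1 parent in the hybrid's place. The draws were also free to mix replicate numbers, which pair the samples. Of all 108 splits that part every replicate pair, 9 gave as many genes as the real one with the block in each hybrid (real 293 and 165, highest others 3535 and 3646). The 8 others each put all 3 libraries of 1 parent in the hybrid's place, where the parental difference alone gives many genes, so this share does not decide about chance. Among the remaining splits the highest count was 0 for Col/C24 and 1 for C24/Col.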

How the results depend on the processing

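The count-based normalizations and tests and the thinning of parents to equal totals planned beforehand were not run, since the values are RPKM. Scaling, its combination with the block, the ribosomal RNA covariate and the removal of 4 libraries were chosen after seeing the data. Of 84 calls of named genes repeated 760 times under other settings, 648 kept direction and threshold, 109 lost the threshold and 3 reversed. Of 537 repeats without 1 replicate, 378 were kept, 159 lost the threshold and 0 reversed. Without the 4 libraries above 2% ribosomal RNA, Col, Col/C24 and the mid-parent are left with 1 library or profile each, assumed to vary like the other groups, so lower counts there do not show a dependence on ribosomal RNA. There FLC stood at 0.85 and 0.81 and AGL20 at -1.95 and -1.93 against the mid-parent, close to the full fits. Depth limits values under about 0.13 RPKM. The cause of the changes below was not tested, except that fewer libraries, or a covariate that overlaps the groups, raise the errors.

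For C24 against Col the count was 929 at a 2-fold minimum, 7490 with the replicate block, 7936 with scaling and block, 2016 with the ribosomal RNA covariate and 1370 without the 4 libraries. Without 1 replicate it ran from 3190 (without Col replicate 2) to 3343. Col/C24 against the mid-parent (6) gave 519 with the block, 156 with the geometric mid-parent, 126 with scaling and block, 2 with the covariate and 0 without the 4 libraries, and 1 to 2 without 1 replicate. C24/Col against the mid-parent (9) gave 4 at 2-fold, 282 with the block, 186 with the geometric mid-parent, 582 with scaling and block, 2 with the covariate and 0 without the 4 libraries, and 1 to 2 without 1 replicate.

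Outside both parents, Col/C24 (20) gave 32 without a filter, 1 at 2-fold, 293 with the block, 12 with scaling, 127 with scaling and block, 3 with the covariate and 0 without the 4 libraries, and 5 to 38 without 1 replicate. C24/Col (21) gave 32, 4, 165 with the block, 30 with scaling (within 1.5 times), 243, 3 and 2 under the same settings, and 7 to 20 without 1 replicate. The count between the hybrids was 0 in every fit run. All genes called without the block were also called with it, in the same direction.

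Hybrid position moved to 0.525 (Col/C24) and 0.504 (C24/Col) for genes higher in Col at 4-fold, and to 0.513 and 0.455 in Col/C24 with scaling. Without 1 replicate it stayed within 0.537 to 0.584 and 0.392 to 0.438 in Col/C24, and 0.518 to 0.53 and 0.449 to 0.506 in C24/Col.

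Against the geometric mid-parent AT3G28320 reversed to 0.64 in both hybrids and AT1G67865 to 0.11 in C24/Col, by construction, since a large gap between parents puts the geometric mean below the arithmetic one. Between the hybrids the median of the photosynthesis list (0.01) ran from -0.037 to 0.11 without 1 replicate and its camera test, part of the limma package, reversed without Col/C24 replicate 2. The heat shock median (-0.103) ran from -0.782 to 0.867 and was 1.028 without the 4 libraries, where the glucosinolate median was 0. In Col/C24 against the mid-parent the photosynthesis median (0.029) ran from -0.075 to 0.093, and the cell division list reversed against other genes without the 4 libraries, at a median of -0.112.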

Other observations

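The test of the flowering regulators below was chosen after the result was seen.

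Beyond heat shock genes, XTH18, a cell wall enzyme gene, stood at 107 ± 56.7 RPKM in the libraries of replicate 1 (SD, n = 4) against 4.31 ± 1.55 and 6.08 ± 2.37 in replicates 2 and 3. There 15 of 21 immune receptor genes were higher (camera adjusted p = 1.39e-09, and 0.132 with an estimated correlation) and 11 of 15 chlorophyll synthesis genes were lower (0.000254, and 0.401 with an estimated correlation). Replicates 3 and 2 differed in 2242 genes.

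Seed storage transcripts were high in 3 hybrid libraries. CRU3 stood at 23.4 RPKM in Col/C24 replicate 1, 12.03 in C24/Col replicate 1 and 77.8 in C24/Col replicate 3.

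AGL20 (SOC1) was lower in Col/C24 than in both parents, a call lost without any of 5 single libraries, while in C24/Col its difference from C24 did not pass (-0.78, adjusted p = 0.0685). With the replicate as a block and all libraries it passed in both hybrids (limma adjusted p = 9.7e-06 and 2.92e-05). A candidate explanation is that the hybrids hold repressors from both parents, FLC at the C24 level and MAF1 (FLM) at an intermediate level. MAF1 was higher in the hybrids than in C24 by log2 fold changes of 1.89 and 1.88 (limma adjusted p = 6.48e-07 and 6.6e-07). This does not decide the question, since these levels prompted the explanation and most genes that differ between the parents were intermediate in the hybrids.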
